A study of Bifidobacterium longum with 6 samples.

How the data were processed

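RNA was sequenced from 2 strains of Bifidobacterium longum, a gut bacterium, named W13 and W13R in the labels, with 3 libraries per strain. Per the labels' protocols, total RNA was treated with DNase I, depleted of ribosomal RNA, fragmented and made into strand-specific libraries of 200 to 300 bp fragments, which were read as pairs of 150 bp on an Illumina NovaSeq. The submitters' processing notes name Trimmomatic and edgeR, without a version or a role. The aligner, the counting program, its strand setting, the genome and the annotation are not given in the sources used here.

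The deposited table holds raw counts per gene, not normalized, for 1960 genes and 6 libraries, with 0 columns of other samples and 0 rows that name no gene. Each column was assigned to a sample by its name, which matches the strain and number in the sample title. All 11760 counts were even (0 odd values), so that each read pair seems to have added 2 to a gene. Some sets of genes had nearly equal counts in both strains and may not be separate measurements, which was not tested. The counts were tested as deposited, and halved counts were run as an alternative. The gene identifiers run from W13_0002 to W13_1961. They therefore carry the name of W13 for both strains. Genes that W13R alone carries were not analysed here, and W13R reads that differ in sequence from the reference used may have been counted less completely.

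The identifiers could not be given gene names. Of them, 0 matched a gene identifier, locus tag, synonym or accession among the 2036 genes of the reference table, which describes another strain of the species, and the count table pairs no identifier with a symbol or a product. Gene lists for exopolysaccharide synthesis and for other functions had been fixed before the data were examined, as had the rules, tests and alternatives unless stated otherwise. None of these lists could be applied, so that no list was tested. For the case of identifiers without names the rule allowed 4 genes to be named: the 2 with the largest rise and the 2 with the largest fall among genes with an adjusted p under 0.05, a mean of at least 20 CPM over the 6 libraries and no overlap between the values of the strains. The other genes are described as groups.

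W13R was compared with W13 by edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3; robust fit, TMM factors, Benjamini-Hochberg adjustment over the genes tested, threshold 0.05). Its filter for low counts at default settings left 1886 genes and removed 74. Fold changes are W13R over W13 on the log2 scale. Standard errors were taken from the fold change and the F statistic. TMM-normalised CPM are CPM on the library size multiplied by its TMM factor. Shares are percentages of the total count of a library and carry no TMM factor, unlike the fold changes. Values per library were compared by a two-sided exact permutation test, which with 3 libraries against 3 has 20 arrangements and cannot go below p = 0.1. A gene was counted as detected in 1 strain only when the libraries of the other strain together held at most 3 counts, a floor set before the pairs were seen to count as 2, and its own libraries at least 30. Neighbouring genes were defined by consecutive identifier numbers. The number of neighbouring pairs called in the same direction was compared with 10000 permutations of the calls over the genes (one-sided), and runs of at least 3 such genes were listed. The rows of the table depart from the order of the numbers at 19 places. Coordinates, strands and gene lengths were not used here.

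The test was run on simulated counts drawn from the means, library sizes and common dispersion of this comparison. In these, 200 genes were changed by at most 4-fold, as often up as down. A shift in composition as large as that between these strains was not simulated. With pairs counted as 2, the test called 94% of the genes changed 1.5-fold, 46% of those changed 1.25-fold and 0.357% of the unchanged genes, over 1883 genes. In a second run each deposited count was drawn as a separate pair, so that it held more pairs than were sequenced. There these shares were 96%, 64% and 0.655% over 1880 genes. Because the depths differ, the 2 runs do not compare ways of counting pairs. When all 1886 genes were changed 1.5-fold, 44.4% of the least abundant 10% were called. The neighbour permutation test gave p = 0.57 for simulated random calls and p = 1e-04 for 30 planted runs. Far fewer genes were called in these simulations than in the data, with 39.54 and 76.07 pairs expected against 613. The permutation test was thus not tried at the density of the real calls. The alternatives were RLE factors, upper-quartile factors, library size only, no low-count filter, a filter at 10 CPM in 3 libraries, DESeq2 (1.42.0), limma-voom (limma 3.58.1), the replicate number as a block, each library left out in turn, other thresholds and other floors.

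Total counts ran from 10300780 to 10838532 in W13 and from 12703222 to 14307454 in W13R. The limit that a count of 0 allows is 3 read pairs, which were counted as 6, and corresponds to 0.419 to 0.582 CPM, for counting error only. Library pairs within a strain differed by more than sampling noise. The chi-square statistic per degree of freedom of their halved counts was 4.84 to 29.1, and no library was counted as a copy of another. It was 4.84 between W13 replicates 1 and 3 and 29.1 in both pairs with W13 replicate 2. Among the W13R libraries it was 10.3 to 13.5. The labels do not say whether the 3 samples of a strain came from separate cultures. The p-values then measure only the spread between these samples, which may be technical.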

Results

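The transcriptomes of 2 strains of the gut bacterium Bifidobacterium longum, W13 and W13R, were measured by RNA sequencing, with 3 libraries per strain. The title of the series sets the comparison beside the structure of the exopolysaccharide (EPS) of both strains, the polysaccharide that such bacteria carry on or release from their surface. How W13R was obtained and how the cells were grown are not given in the sources used here. The count table lists 1960 genes. The mean total count was 10490000 ± 300000 (SD, n = 3) in W13 and 13270000 ± 902000 (SD, n = 3) in W13R, and each read pair seems to have been counted as 2.

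The counts of W13 were concentrated in few genes and those of W13R were spread more evenly. The 10 most abundant genes of each library held 27.9% ± 0.925 of the counts in W13 and 11.8% ± 0.0964 in W13R (SD, n = 3). The 100 most abundant held 61.2% ± 0.838 in W13 and 44.0% ± 0.485 in W13R. In both measures the libraries of the strains did not overlap (exact permutation test, two-sided, p = 0.1, the smallest that this design allows). The median gene had 98.1 ± 2.88 CPM (counts scaled to library size) in W13 and 159 ± 2.9 in W13R (SD, n = 3). Within a strain the log2 CPM of library pairs correlated across genes at Pearson's r of 0.9953 to 0.9973, and between the strains at 0.8305 to 0.8423. Genes are not independent replicates in these values.

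**Figure D1:**
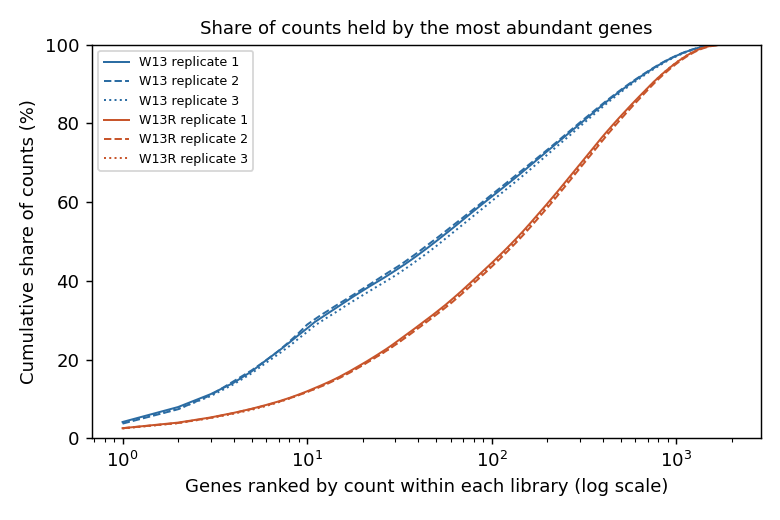
The cumulative share of counts (%, y axis) is plotted against the rank of the genes by count within each library (x axis, log scale), with 1 line per library. At rank 10 the W13 libraries stood at 27.01% to 28.86% and the W13R libraries at 11.75% to 11.93%.

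The genes that led the libraries were different in the 2 strains. The 10 genes with the highest mean CPM in W13 and the 10 with the highest in W13R had 0 members in common, and the lists of 100 shared 50. All 10 leading genes of W13 were lower in W13R, with log2 fold changes of -10.97 to -2.88, and their joint share of the counts went from 27.9% ± 0.93 in W13 to 1.69% ± 0.082 in W13R (SD, n = 3). Of the 10 leading genes of W13R, 9 were higher than in W13 and 1 was not past the threshold, with a median log2 fold change of 0.68. These 10 genes held 4.33% ± 0.028 of the counts in W13 and 11.8% ± 0.097 in W13R. With RLE factors 8 of the 10 were higher, and with library size alone all 10 were. Each list was chosen by its level in 1 of the strains compared.

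Most genes differed between W13R and W13. Of 1886 genes tested, 1547 (82%) passed an adjusted p of 0.05 (edgeR's quasi-likelihood test, Benjamini-Hochberg), of which 789 were higher and 758 lower in W13R. The 3 values of one strain did not overlap the 3 of the other in 1582 genes (83.9%), where chance gives 10%. The genes that were higher together held 19.2% ± 0.707 of the counts in W13 and 61.1% ± 0.299 in W13R, and those that were lower held 74.8% ± 0.76 and 27.6% ± 0.296 (SD, n = 3). The 339 genes not past the threshold held 6.05% ± 0.0897 in W13 and 11.25% ± 0.00122 in W13R. A larger share in W13R is therefore not by itself a rise on the TMM scale. The median standard error of a log2 fold change was 0.093. The split by direction depended on the scaling of the libraries. Higher genes made up 51% of the calls with TMM factors, 61.9% (993 higher, 612 lower) with upper-quartile factors and 74.3% (1261 higher, 437 lower) with library size alone. The median log2 fold change of all genes was 0.07, 0.41 and 0.96 under these 3 scalings, and the fold changes given here are relative to the TMM scaling.

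**Figure D2:**
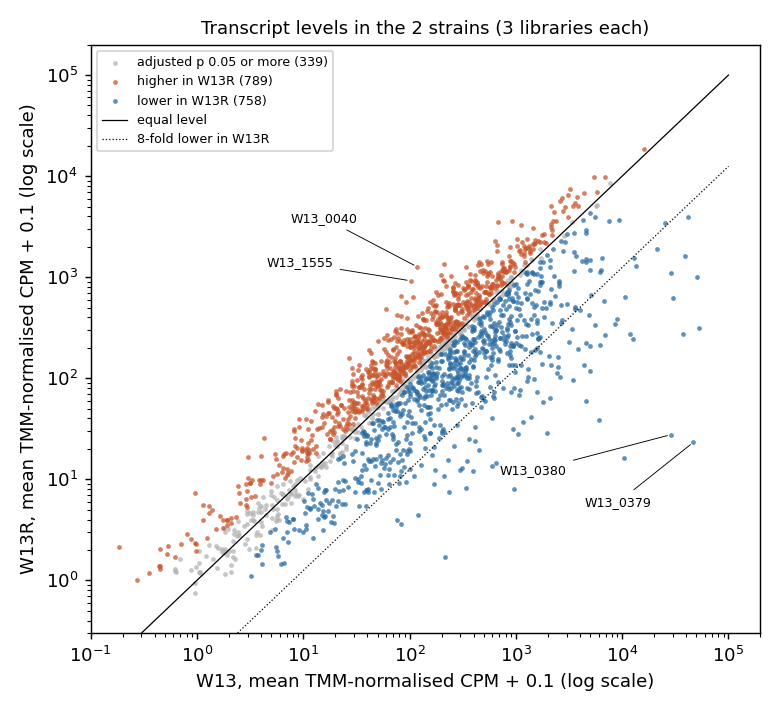
Each point is a gene, with its mean TMM-normalised CPM over 3 libraries in W13 (x axis) and in W13R (y axis), both on log scales after a small constant was added. Of the genes, 789 were called higher and 758 lower in W13R, and the points far below the 8-fold line on the right are genes that were abundant in W13.

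The falls were larger than the rises. A change of at least 2-fold was found in 325 higher and 483 lower genes, of at least 4-fold in 40 and 224, and of at least 8-fold in 4 and 98. The 4 became 9, 7 and 11 without W13 replicates 1, 2 and 3, and 7 without W13R replicate 3. In these fits the low-count filter left more genes, 1911 to 1914 against 1886. At 32-fold or more there were 0 higher and 24 lower genes. With library size alone, which moves every fold change upwards, 29 genes were higher and 59 lower by at least 8-fold. The 98 genes that were lower by 8-fold or more held 43.9% ± 0.778 of the counts in W13 and 3.14% ± 0.131 in W13R (SD, n = 3). Of these, 41 lay in the top 10% of genes by mean abundance, where the interquartile range of the log2 fold changes was 3.19. In the other 9 abundance classes of equal size it was 1.41 to 2.17, with 0 to 14 such genes each. In the same top class 107 genes were lower and 68 higher.

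The largest falls were those of W13_0379 and W13_0380, a pair of neighbouring genes. W13_0379 was the third most abundant gene of W13, with 46600 ± 4860 TMM-normalised CPM and counts of 335874 to 382932 per library, and had 23.1 ± 3.69 TMM-normalised CPM and counts of 348 to 550 in W13R (SD, n = 3). Its log2 fold change was -10.97 with a standard error of 0.166, a difference of 2010-fold (edgeR adjusted p = 2.67e-23). W13_0380 had 28740 ± 3850 TMM-normalised CPM in W13 and 27.6 ± 2.8 in W13R, with a log2 fold change of -10.02 and a standard error of 0.153 (edgeR adjusted p = 2.67e-23). W13_0379 made up 3.41% of the counts of W13 and 0.00316% of those of W13R, and W13_0380 2.1% and 0.00377%. What these genes encode was not analysed here.

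The largest rises among genes with at least 20 CPM were those of W13_0040 and W13_1555. W13_0040 went from 118 ± 6.13 TMM-normalised CPM in W13 to 1266 ± 66 in W13R (SD, n = 3), with counts of 868 to 974 and of 20822 to 24718 per library. Its log2 fold change was 3.42 with a standard error of 0.0848 (edgeR adjusted p = 5.4e-20). W13_1555 went from 102 ± 11.7 to 921 ± 49.8 TMM-normalised CPM, a log2 fold change of 3.17 with a standard error of 0.0926 (edgeR adjusted p = 1.19e-18). The other two genes that were higher by 8-fold or more lay under 20 CPM. In abundance W13_0040 ranked 1040 in W13 and 120 in W13R, and W13_1555 ranked 1085 and 185.

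**Figure D3:**
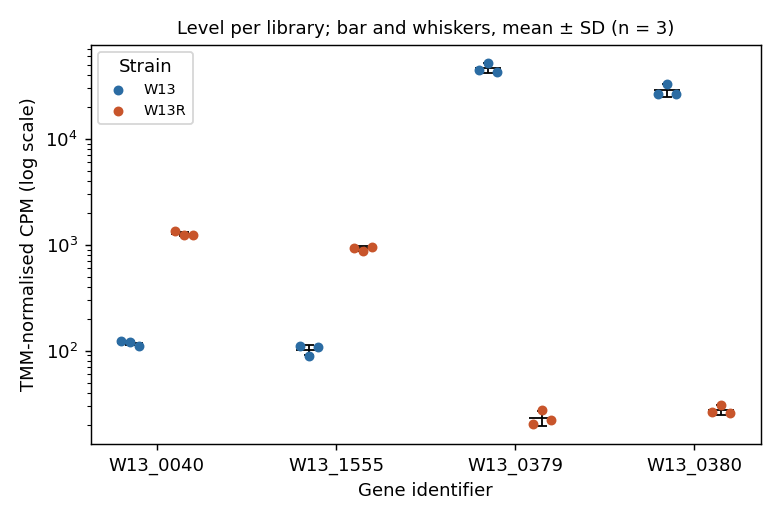
TMM-normalised CPM (y axis, log scale) are plotted for each of the 4 named genes in each library, with the mean and SD of 3 libraries per strain as a bar and whiskers. W13_0379 and W13_0380 stood at 26350 or more in every W13 library and at 30.78 or less in every W13R library, and the libraries of W13_0040 and W13_1555 did not overlap in the other direction.

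Genes with consecutive identifiers changed together. Of 1821 neighbouring pairs of tested genes, 929 were called in the same direction, against 613 ± 17.8 (SD) in permuted orders, whose highest value was 678 (one-sided permutation test, p = 1e-04, the smallest that 10000 permutations can give). The p describes the order of these calls only, since genes are not independent replicates. The log2 fold changes of direct neighbours correlated across genes at r = 0.5, those of genes 2, 3 and 5 places apart at 0.31, 0.21 and 0.06. Runs of at least 3 neighbouring genes called in the same direction numbered 195, of which 102 were higher and 93 lower in W13R, and held 983 genes, 63.5% of those called. With 82% of the genes called, permuted orders also hold runs, and these were not counted.

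The run that holds W13_0379 and W13_0380 had 11 genes, of which 4 were lower by 7 or more on the log2 scale and the others by less than 3, down to a fall of 0.61. The share of the counts in this run was 6.35% ± 0.57 in W13 and 0.0511% ± 0.0026 in W13R (SD, n = 3). With library size alone 2 of its 11 genes had the opposite sign. W13_1555 lay in a run of 8 higher genes with log2 fold changes of 1.36 to 3.17, whose share was 0.183% ± 0.013 in W13 and 1.29% ± 0.008 in W13R. W13_0040 lay in a run of 5 higher genes with log2 fold changes of 0.23 to 3.42. The longest run of higher genes had 30 members, with a median log2 fold change of 0.57 and a range of 0.48 to 1.22, and its share was 2.45% ± 0.19 in W13 and 6.86% ± 0.2 in W13R. The longest run of lower genes had 25 members, near the middle of the numbering, with a median log2 fold change of -2.23 and a range of -3.9 to -0.89. Its share was small, at 0.15% ± 0.013 in W13 and 0.0527% ± 0.0045 in W13R, and with library size alone 1 of its genes had the opposite sign. It lay in a wider stretch of 69 identifiers, found by joining lower runs no more than 10 identifiers apart, a rule chosen after the values were seen. Of the 68 genes tested there, 59 were lower, 3 were higher and 6 were not past the threshold, with a median log2 fold change of -1.69. The joint share of these 68 genes was larger in W13R, at 1.99% ± 0.065 against 1.38% ± 0.023 in W13 (SD, n = 3). Within the stretch, the lower runs of 25, 20 and 7 genes had smaller shares in W13R, and those of 3 genes slightly larger ones. The share of the run of 20 was 0.29% in W13 and 0.178% in W13R. The larger joint share thus came from genes of the stretch outside these lower runs. Shares carry no TMM factor, and that of all genes not past the threshold also rose, from 6.05% to 11.25%, by more in proportion. The larger share is thus no sign that the stretch as a whole rose on the TMM scale. The second longest run of lower genes, with 20 members and a median of -1.77, belonged to the same stretch.

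**Figure D4:**
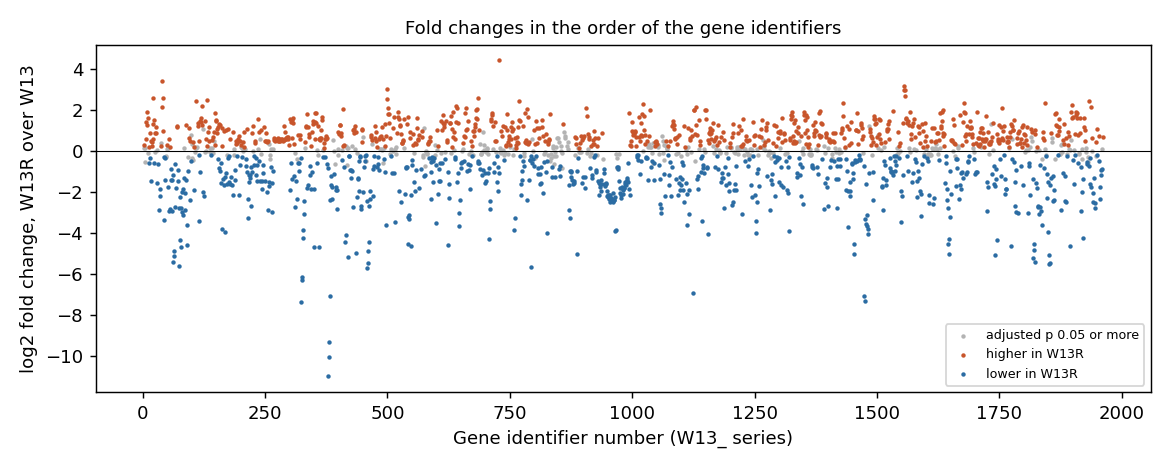
The log2 fold change of each tested gene, W13R over W13 (y axis), is plotted against its identifier number (x axis), coloured by the call. Of the 98 genes lower by 8-fold or more, 76 lay in runs of at least 3 lower neighbours. Of all called genes, 63.5% lay in runs of either direction. The longest run of lower genes, with 25 members, lies near the middle of the axis.

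Few genes were detected in 1 strain only, and none of them was abundant. In W13R 9 genes had 30 to 116 counts over the 3 libraries while W13 had at most 3 counts, which is 1 read pair. In W13 the corresponding number was 0. With at most 6 counts, or 3 read pairs, in the other strain the numbers were 21 and 0. Of the 9 genes, 1 entered the edgeR test, and it was higher in W13R. At most 3 counts were found for 39 genes in W13 and for 2 genes in W13R, and these 2 were at that level in both strains. The depth relative to the TMM scaling was 2.36 times larger in W13R. When the W13R pairs were thinned to the W13 depth in 100 random draws, a median of 9 genes (range 4 to 15) had at most 3 counts, and a median of 1 gene (range 0 to 3) met the rule for detection in W13R only. Without W13R replicate 2, the deepest library, the 9 genes became 1. Without W13 replicates 1, 2 or 3 the number was 14, 14 or 17.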

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

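The number of changed genes, 1547 of 1886, stayed between 1467 and 1698 under each change of scaling, filter and test, and between 1496 and 1562 with single libraries left out. Requiring a 2-fold change left 808 genes (325 higher, 483 lower). The directions depended on scaling: with library size alone 1261 genes were higher and 437 lower, 29 and 59 of them by 8-fold or more, since that scaling moves the median log2 fold change to 0.96. Of the genes called under both scalings, 1226 of 1396 then kept their sign. Genes higher by 8-fold or more, 4 with TMM factors, numbered 7 with upper-quartile factors, 9 without a low-count filter and 8 with DESeq2. At a filter of 10 CPM in 3 libraries they numbered 4. With single libraries left out they numbered 5 to 11 (9, 7 and 11 without W13 replicates 1, 2 and 3, and 7 without W13R replicate 3). In those named fits the low-count filter left 1914, 1914, 1914 and 1911 genes, against 1886 with all libraries. The cause was not tested. Those lower by 8-fold or more, 98 with TMM factors, numbered 79 with upper-quartile factors and 95 to 99 with single libraries left out. Genes detected in W13R only, 9 at a floor of 3 counts, numbered 1 at a floor of 0, 21 at a floor of 6, 38 at a floor of 10 and 1 to 17 with single libraries left out, by the construction of the floor; in W13 only they numbered 0 to 0. The 4 named genes kept direction and significance in all 64 of their alternatives. The excess of neighbouring pairs, 1.52 times the expected number, was 1.51 to 1.54 with single libraries left out. The share of the 10 most abundant genes in W13R minus that in W13 was -16.6 to -15.6 percentage points with single libraries left out. With the replicate number as a block, 1544 genes changed (787 higher, 757 lower); same-numbered libraries did not deviate together (correlations of 0.037, -0.049 and -0.032), and no library correlated best with its own number. Halved counts gave 1545 genes and factors computed without the 10 most abundant genes of either strain gave 1547; these settings, the floor of 6 counts, the counts of 8-fold changes, the shares of the 10 most abundant genes with single libraries left out and the file's gene order were chosen after seeing the data. The planned tests of gene lists were not run, for lack of gene names. In the lowest 10% of genes by abundance 86 of 189 were called, against 141 to 177 in the other classes of equal size; in simulated counts of this comparison (1886 genes, each changed 1.5-fold) 44.4% were called in that class and 93.7% to 100% in the others, so that depth limits calls there.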

Other observations

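The tests below were chosen after the values were seen, except the split of the libraries, which was planned. The split of the 6 libraries by strain gave 1547 changed genes, and the highest of the other 9 splits gave 0 by edgeR's quasi-likelihood test, with 0 to 9 genes at an unadjusted p under 0.05; DESeq2 was not run on them. Only 1 of the 10 splits gave as many genes, and 10 splits are too few for a share under 0.05. Each of the other 9 splits mixes both strains within its groups, so that the strain difference enters the spread and hides changes. Their 0 is therefore no measure of the false calls among the 1547.

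The 98 genes that were lower by 8-fold or more in W13R held 43.9% of the W13 counts. Their median log2 fold change was -4.25 with TMM factors and -3.35 with library size alone, the highest of the scalings tried. The scalings thus differed by less than these falls. The genes were chosen by their falls with TMM factors, and a scaling shifts all genes alike. These values therefore cannot test scaling as a cause. Complete loss of the genes with no carry-over was argued against, since 98 of the 98 had more than 3 counts over the W13R libraries, the lowest 90. Carry-over of W13 material at a single rate would leave each lost gene the same percentage of its W13 share of the library counts. Without TMM scaling that percentage ran from 0.0926% in W13_0379 to 23%, a ratio of 249, where the W13R libraries varied by a median of 8.76% (SD over mean). The 8-fold cut that chose these genes limits the highest percentage, so that the size of the ratio depends on the cut. The percentages still differed by more than the spread of the libraries. Loss with carry-over at a single rate therefore could not hold for all 98. For how many of them it could hold, and rates that differ between genes, were not tested. For W13_0379 it could not be told apart from low expression, because no other gene sets a lower limit on the rate. Also open are a difference in regulation or in culture conditions between the strains, and reads lost to sequence differences from the reference.

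Neighbouring genes changed in the same direction, and 76 of the 98 large falls lay in runs of lower genes. Of all called genes 63.5% lay in runs of either direction, and how many of the 98 would do so in permuted orders was not tested. A slow gradient along the chromosome would leave distant genes correlated too, but the correlation of log2 fold changes was 0.03 at 20 places, against 0.5 for direct neighbours. Reads that overlap the borders of adjacent genes were argued against as the whole cause by the correlation of 0.21 at 3 places, where the highest of 10000 permuted orders gave 0.08, but they may add to that of direct neighbours. Transcription of neighbours from a shared promoter is a hypothesis that stays open, since strands and coordinates were not used here.

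The longest run of lower genes, 25 members near the middle of the numbering, had log2 fold changes close to each other over most of its length, with 17 within 0.5 of the median. A single change in copy number of the whole run would give each gene the same fold change. The fold changes ran from -3.9 (standard error 0.11) to -0.89 (standard error 0.36), and Cochran's Q was 21.9 per degree of freedom over 24 degrees of freedom, so that this could not be the whole cause. For the wider stretch of 69 identifiers around it the value was 52.1. That stretch was joined from these same calls and held 59 lower and 3 higher genes, so that a high value was certain. No conclusion on copy number is drawn from it. A change of copy number in part of the run, or joint regulation, may still underlie it and was not tested.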
